A study of Gallus gallus with 10 samples.

How the data were processed

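Total RNA from whole magnum tissue was extracted with TRIzol, samples with an RNA integrity number above 7 were kept, and libraries were made with a directional (strand-marking) kit, NEBNext Ultra II, per the labels' protocols. The submitters' processing notes name Trimmomatic, HISAT2, Cufflinks and DESeq2 and the chicken genome build GRCg7b. The read counter, its strand setting, the annotation release and the versions of these tools are not given in the sources used here. The authors deposited raw counts per Ensembl gene for 10 libraries, as whole numbers that had not been normalized. A table of the authors' own comparison was also deposited, with columns in the layout of DESeq2 per the file headers. Its log2 fold changes and their standard errors are the authors' values, per the file headers. The p-values and adjusted p-values in it are likewise the authors' own, and an adjusted p that is blank was left blank. The score column of the deposited table is the authors' Wald statistic and was not used in any test. Its mean normalised counts are named as the authors' where they are printed.

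The 10 libraries were grouped by the age in their labels, with 5 hens at 35 weeks and 5 at 50 weeks, and every column of the count table was matched to a sample by the column name given in that sample's description. Symbols were present for 14185 of 29558 genes. Of the gene IDs, 12826 were matched to a RefSeq gene table of the same build, GRCg7b, which was used for coordinates and for which genes overlap or lie within 1 kb of each other. That table has no strand column. Between 39.2% and 42.3% of a library's counts fell in genes without a symbol. Pairs of libraries of 1 age were compared by a chi-square test of their counts and differed by more than sampling noise (at least 3.27 per degree of freedom), with Spearman correlations between 0.816 and 0.922, so each library counts as 1 replicate.

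Differences between ages were tested with edgeR 4.0.16 in R 4.3.3 (filterByExpr with its minimum count of 10, TMM normalization, estimateDisp, robust glmQLFit and glmQLFTest, two-sided), with age as the one term and Benjamini-Hochberg adjustment over all tested genes. The threshold was an adjusted p under 0.05. CPM values are counts scaled by edgeR's cpm function with the library total multiplied by the TMM factor, and errors are SDs over 5 hens. Fold changes are 50 weeks against 35 weeks. The biological coefficient of variation was 0.285. The pipeline was tested on simulated data drawn from the means and library sizes of these libraries. In it 200 genes were made to change 2-fold or 4-fold, and each gene was drawn independently of the others. The shares recovered depend on that number of changed genes and do not give the recovery in the real comparison. Of 1684 simulated genes in the comparison of 50 with 35 weeks, 55.9% of those changed 2-fold and 97.7% of those changed 4-fold were recovered, and 2.86% of the 140 calls were unchanged genes.

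Before the data were examined, 36 gene lists were fixed, 20 of programs of a secreting oviduct and 16 of markers of other cell types, other oviduct segments and tissue handling. Lists with at least 5 tested members, 12 in all, were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over these 12. Camera with an estimated correlation and fry were run beside it. Marker lists were also compared by summed CPM, which was scaled by library totals without the TMM factor and so is not on the scale of the single genes. Shares of counts, summed CPM and distances between hens were tested by exact two-sided permutation over all assignments of the 10 libraries to the ages (Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, figures with matplotlib 3.10.9).

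The rule for naming genes was also fixed beforehand. It names the 8 largest separated changes per direction and the 4 smallest p among genes with a symbol past the threshold. Where fewer than 5 pass in a direction, it names the 8 smallest unadjusted p instead. This last part does not repeat the limit to genes with a symbol. The 8 were taken among genes with a symbol, and genes without a symbol whose p was as small were named beside them after their values were seen. The rule adds every egg white gene with a mean CPM of 10 or more, the 2 members with the smallest p of each list described, and the 5 genes with the highest mean CPM. A gene that this rule names is not reported here. Genes named outside this rule are said to have been picked after their values were seen.

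The other settings, fixed beforehand, were RLE size factors, library totals only, normalization without the egg white genes, no filter on low counts, a filter of CPM of 1 or more in at least 5 libraries, DESeq2 1.42.0, limma-voom with sample weights, a block for the replicate number, a fold change of at least 2, a prior count of 0.5, other forms of the share and of the distance, and leaving out each library in turn. Leaving out the 3 libraries that stood apart on the first principal component was added after seeing the data. Other groupings were examined by refitting 100 of the 126 splits of the 10 libraries into 5 and 5.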

Results

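RNA was sequenced from the magnum, the segment of the hen's oviduct that secretes egg white around the yolk, in broiler breeders (Gallus gallus) at 2 ages. The question set by the series was how the magnum transcriptome differs between peak lay, at 35 weeks of age, and declining lay, at 50 weeks. Each age had 5 hens, every library came from a bird with its own number, and whole tissue was taken while an egg lay in the magnum. The sample titles also carry the words shell gland, the name of a later oviduct segment, whereas the tissue and source labels give the magnum. The deposited table held 29558 genes, of which 15792 had a count in any library and 3405 had a count in all 10. Library totals lay between 188271 and 258195 counts (median 220938), and the most counted gene took 7.24% to 11.8% of a library. At this depth a count of 0 allows a level of up to 11.6 to 15.9 CPM (the count unit scaled to a common library size), depending on the library, and this limit covers counting error only.

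Egg white protein genes were lower at 50 weeks. Of 15 members with enough counts to be tested, 12 had negative fold changes, the median log2 fold change was −0.66, and the list as a whole lay below the other genes by camera (adjusted p = 7.1e-07). With an estimated correlation the adjusted p was 0.069. None of the members passed over all genes in the main fit of edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Adjusted over the list alone 9 passed, all of them lower. With either looser filter on low counts, edgeR called TF, SPINK7, OVALY and RBP over all genes. With CPM of 1 or more in at least 5 libraries it also called LYZ. At an unadjusted p under 0.05 there were also 9, and over all genes DESeq2 called 5 members and limma with sample weights 2. TF, the iron-binding ovotransferrin, averaged 6961 ± 1085 CPM (SD, n = 5) at 35 weeks and 3930 ± 766 CPM at 50 weeks, a log2 fold change of −0.83 (SE 0.17, adjusted p = 0.0989 over all genes). SPINK7, which encodes the protease inhibitor ovomucoid, averaged 6087 ± 1412 and 3547 ± 816 CPM (log2 fold change −0.78). OVALY, the ovalbumin-related protein Y, averaged 2436 ± 206 and 1451 ± 260 CPM (log2 fold change −0.75), and its neighbour OVALX averaged 792 ± 75.5 and 558 ± 44.4 CPM (−0.50). OVAL, the gene of ovalbumin, the main egg white protein, had the smallest of the 9 fold changes, with 27193 ± 3359 CPM at 35 weeks and 20999 ± 3523 CPM at 50 weeks (−0.37). The remaining 4 were the riboflavin-binding protein gene RBP (log2 fold change −0.85), the lysozyme gene LYZ (−0.73), ORM1 (−0.66) and the beta-defensin gene AvBD11 (−0.997). OVALY, TF, OVALX and SPINK7 were separated between the ages, with every hen at 35 weeks above every hen at 50 weeks. Chance separates 0.794% of genes, and 29 of all 1773 tested genes (1.64%) were separated.

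The other egg white genes did not pass. The fold changes of SPINK5 (ovoinhibitor, 651 ± 29.5 and 652 ± 177 CPM), CST3 (cystatin, 930 ± 142 and 958 ± 198 CPM) and CLU (clusterin, 381 ± 95.9 and 363 ± 18.7 CPM) were within 1 SE of 0, at 0.0033, 0.05 and −0.07 on the log2 scale, and their signs depended on the libraries and test used. OVST (ovostatin) had a log2 fold change of −0.21, EXFABP of −0.97 with an SE of 0.56, and MUC6, a mucin gene, of 0.47 with an SE of 0.50. AVD (avidin, 65.8 ± 42.8 and 25.9 ± 12.8 CPM), SERPINB6 (13.9 ± 8.49 and 14.2 ± 12.4 CPM) and VMO1 (2.14 ± 2.93 and 18.8 ± 26 CPM) had too few counts to be tested. Together the 23 egg white genes in the table held 4.81% ± 0.585 (SD, n = 5) of all counts at 35 weeks and 3.51% ± 0.518 at 50 weeks. The difference of −1.30 percentage points had an exact two-sided permutation p of 0.00794, the smallest that the assignments of 5 hens to each age can give. Without OVAL the shares were 2.13% ± 0.308 and 1.38% ± 0.201 (exact permutation p = 0.00794). Replicates 1 and 2 at 35 weeks and replicate 4 at 50 weeks stood apart from the other 7 libraries in their overall profile. Without these 3 libraries, a comparison chosen after seeing the data, the median log2 fold change of the list was −0.39 (camera adjusted p = 0.00558, and adjusted p = 0.737 with an estimated correlation), 3 members passed adjusted over the list alone, and the difference in share was −0.848 points (exact permutation p = 0.0571 over 35 assignments). Without replicate 1 at 35 weeks alone, 5 members passed.

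**Figure D1:**
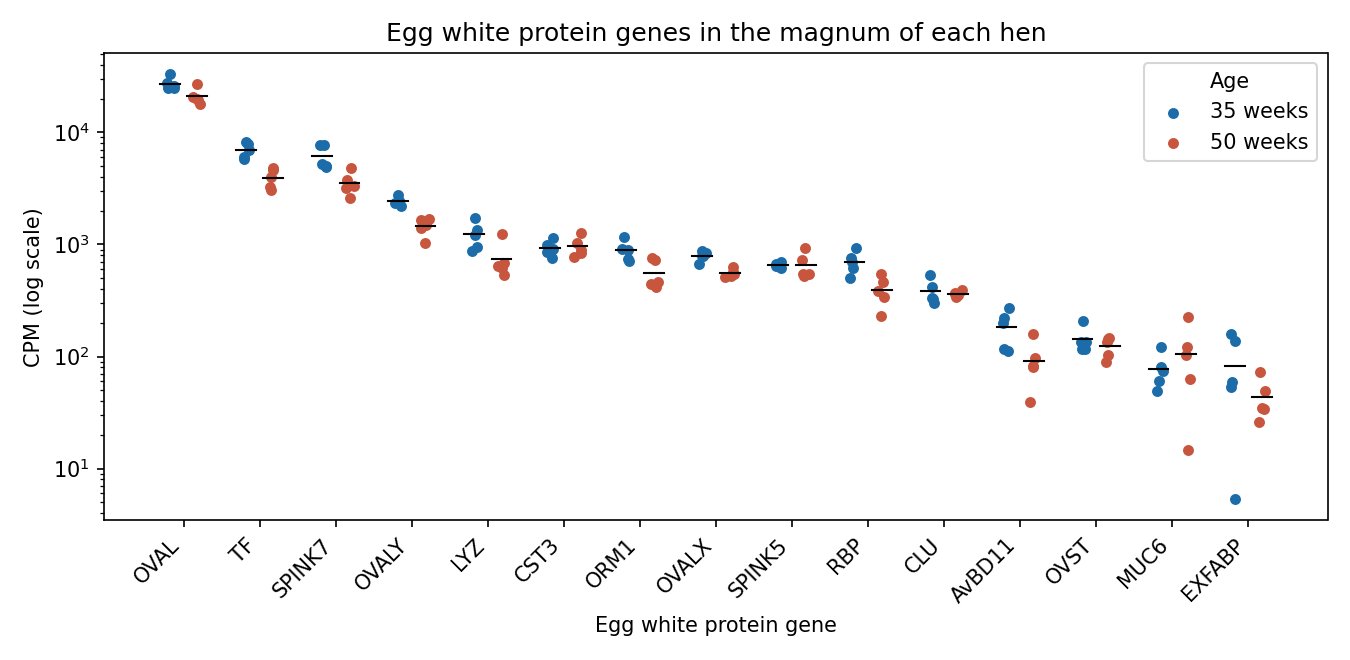
CPM on a log axis of the 15 tested egg white protein genes, ordered by level, with 1 point per hen (5 at each age) and a black line at each mean. TF averaged 6961 CPM at 35 weeks and 3930 CPM at 50 weeks with no overlap between the ages, while the CST3 points of both ages overlap.

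The list of endoplasmic reticulum chaperones and unfolded protein response genes, which fold and monitor secreted proteins, also lay below the other genes at 50 weeks by camera (adjusted p = 0.0457), with 9 of 10 tested members negative. With an estimated correlation the adjusted p was 0.248. None of the members passed over all genes in edgeR's main fit, and 3 had an unadjusted p under 0.05. Adjusted over the list alone 3 passed, 2 lower and 1, DNAJC3, higher. Over all genes DESeq2 and limma each called 1, HSP90B1, as did edgeR with either looser filter on low counts. This chaperone of the HSP90 family averaged 165 ± 40.8 CPM at 35 weeks and 67.2 ± 30.2 CPM at 50 weeks (log2 fold change −1.29, SE 0.30), and the calcium-binding chaperone gene CALR averaged 470 ± 72.7 and 309 ± 62.3 CPM (−0.61, SE 0.18). DNAJC3, a co-chaperone gene named after its values were seen, went the other way, from 251.9 ± 26.4 to 385 ± 119 CPM (0.61, SE 0.21). The call for this list was lost without the 3 libraries that stood apart (adjusted p = 0.753). It was also lost on leaving out replicate 1 (0.0959) or 2 (0.143) at 35 weeks, or replicate 1 (0.0506), 3 (0.0586) or 4 (0.0786) at 50 weeks.

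**Figure D2:**
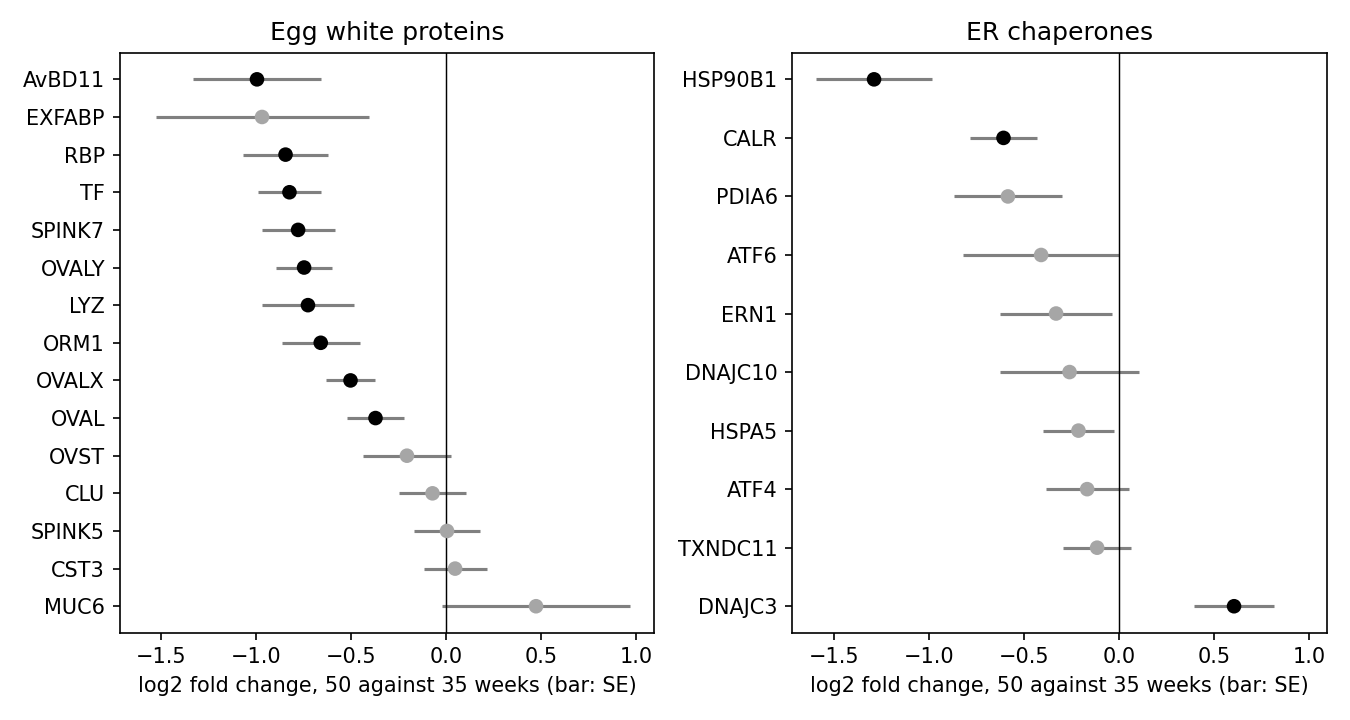
Log2 fold change (50 against 35 weeks, with its SE as a bar) of each tested egg white gene (left) and endoplasmic reticulum chaperone gene (right), black where the gene passed adjusted over its list alone and grey where it did not. Of 15 egg white genes 12 lie below 0, from AvBD11 at −0.997 to MUC6 at 0.47, and of 10 chaperone genes DNAJC3 is the one above 0.

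Of the other 10 lists with at least 5 tested members, none passed by camera. Cytosolic ribosomal proteins had 10 of 14 members negative, with a median log2 fold change of −0.25 (adjusted p = 0.0621). RPL37A averaged 86.6 ± 25.1 CPM at 35 weeks and 52.3 ± 6.72 CPM at 50 weeks (−0.73), and RPL6 averaged 127 ± 30.6 and 79.9 ± 24.5 CPM (−0.67). Without the 3 libraries that stood apart, the direction of this list turned (adjusted p = 0.985). Leaving out replicate 4 or 5 at 35 weeks, or 1, 2 or 5 at 50 weeks, took it past the threshold, with adjusted p between 0.00759 and 0.0366. Translation initiation and elongation factors had 5 of 6 negative (adjusted p = 0.126), among them EIF2S1 (log2 fold change −0.90) and EIF3A (−0.57). Oxidative phosphorylation subunits were split 5 against 5 (adjusted p = 0.702), with ATP5PF at −0.57 and NDUFB9 at −0.46. Steroid receptors and their cofactors had an adjusted p of 0.575, with HSD11B2, which inactivates glucocorticoids, at −0.54 and the chaperone gene HSP90AA1 at 0.40. Translocon, signal peptide and glycosylation genes had 4 positive and 4 negative members (adjusted p = 0.89), with SRP14 at −0.21 and SSR2 at 0.22. Antioxidant defence (adjusted p = 0.759) included GPX8 at 1.05 (0.27 without replicate 4 at 50 weeks) and the ferritin gene FTH1 at −0.62. Interferon response and antigen presentation (adjusted p = 0.703) included DMA at −0.60 and TAPBP at −1.08. The adjusted p was 0.89 for cell cycle and proliferation (BIRC5 −0.24, KIF20A 0.21), 0.89 for heat shock proteins (DNAJA4 −0.57, HSPE1 0.34) and 0.86 for ciliated epithelium (CCDC65 −0.53, SPEF2 0.52). The list of heat shock proteins had a positive median (0.10) and a negative mean (−0.06), the oxidative phosphorylation list a positive median (0.02) and a negative mean (−0.09), and the translocon list a positive median (0.01) and a negative mean (−0.0065).

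The other 24 lists had fewer than 5 tested members and no member past the threshold over all genes. Vesicle traffic had 3 tested members, ion and water transport 4, amino acid transport and aminoacyl-tRNA synthesis 2, extracellular matrix 3, senescence and secreted inflammatory factors 3, apoptosis and autophagy 4, lipid and sterol metabolism 2 and the circadian clock 0. Antimicrobial peptides and innate sensors had 3, of which AvBD11, also an egg white gene, passed adjusted over the list alone (LITAF was at 0.41). Markers of other cell types were compared by their summed CPM, with exact two-sided permutation tests adjusted over 16 lists, and none passed. B and plasma cell markers summed to 69.9 ± 15 CPM at 35 weeks and 113 ± 26.7 CPM at 50 weeks (exact permutation p = 0.0159, adjusted p = 0.254). Thrombocyte markers, made up mostly of NFE2 (log2 fold change 0.13), summed to 2700 ± 207 and 3034 ± 284 CPM (exact permutation p = 0.0397, adjusted p = 0.317). Smooth muscle markers summed to 288 ± 111 and 224 ± 33.4 CPM, fibroblast markers to 185 ± 41.1 and 205 ± 24.4 CPM, endothelial markers to 881 ± 163 and 819 ± 166 CPM, and ciliated epithelium markers to 3584 ± 379 and 3356 ± 381 CPM. General epithelium, T and NK cells, macrophages and dendritic cells, heterophils and granulocytes, erythrocytes, nerve and glia, adipocytes and mesothelium, shell gland, isthmus and infundibulum, and immediate early genes had adjusted p between 0.694 and 0.992.

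Over all genes, TIMM13, which encodes a chaperone of protein import into mitochondria, was the 1 gene of 1773 tested that passed an adjusted p under 0.05 in edgeR's quasi-likelihood test. It lies on chromosome 28 at 1041705 to 1042291 (GRCg7b), within 1 kb of TMPRSS9 in the annotation used, and averaged 666 ± 179 CPM (SD, n = 5) at 35 weeks and 190 ± 38.5 CPM at 50 weeks. Its log2 fold change was −1.81 (SE 0.21, adjusted p = 8.7e-04), every hen at 35 weeks lay above every hen at 50 weeks, and it passed in all 20 fits that were run. No gene passed in the higher direction. At an unadjusted p under 0.05 there were 186 genes, 79 higher and 107 lower, where 88.7 would arise by chance if nothing differed, and scaling by library totals alone gave 108 higher and 83 lower. DESeq2 called 20 genes (6 higher, 14 lower), limma with sample weights called 12 (3 higher, 9 lower), and edgeR without a filter on low counts called 36 (13 higher, 23 lower). Without replicate 4 at 50 weeks edgeR called 12 genes, without the 3 libraries that stood apart 43, and without replicate 1 or 4 at 35 weeks or replicate 5 at 50 weeks 2 each.

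As fewer than 5 genes passed in either direction, the genes with a symbol that had the 8 smallest unadjusted p in each direction are given, with the genes without a symbol whose p was as small. Apart from TIMM13 none of them passed in edgeR's main test. With either looser filter on low counts edgeR also called AGK, POMGNT2, NUDT2, OVALY, TF, SPINK7, HSP90B1, LRRN3, ENSGALG00010018678 and ENSGALG00010030072. With CPM of 1 or more in at least 5 libraries it also called HDGFL3 and ENSGALG00010006141. DESeq2 also called ENSGALG00010030072, VASH1, AGK, UTP3, POMGNT2, OVALY, TF, SPINK7, ZMYM3, SENP8 and HSP90B1, and limma with sample weights called ENSGALG00010014349, AGK, UTP3, POMGNT2, OVALY, TF and HSP90B1. With higher values at 50 weeks were VASH1, an inhibitor of vessel growth (170 ± 25.2 and 287 ± 49.9 CPM, log2 fold change 0.75), the lipid kinase gene AGK (1944 ± 367 and 3151 ± 667 CPM, 0.70) and UTP3, involved in ribosome assembly (7413 ± 3312 and 15920 ± 3806 CPM, 1.10). The glycosyltransferase gene POMGNT2 (1622 ± 466 and 3338 ± 1206 CPM, 1.04), NHERF4 (1.00), HDGFL3 (0.64), the cilium transport gene IFT43 (0.57) and NUDT2 (0.76) completed those with a symbol, and those without were ENSGALG00010006141 (1.41), ENSGALG00010030072 (1.40) and ENSGALG00010018678 (1.27). With lower values, besides TIMM13, HSP90B1, OVALY, TF and SPINK7, were LRRN3 (108 ± 40.2 and 33.4 ± 14.7 CPM, −1.70), SENP8, a protease that acts on the ubiquitin-like protein NEDD8 (978 ± 96.3 and 637 ± 113 CPM, −0.62), and the zinc finger gene ZMYM3. ZMYM3 averaged 530 ± 504 and 30.6 ± 17.5 CPM, a log2 fold change of −4.06 with an SE of 0.79. The gene without a symbol was ENSGALG00010014349 (76.8 ± 13.4 and 30.2 ± 3.23 CPM, −1.32). The 5 genes with the highest mean CPM were OVAL, VPS13A (15132 ± 4006 and 23435 ± 10802 CPM) and 3 genes without a symbol. The first of these, ENSGALG00010001532, averaged 97430 ± 5246 and 102180 ± 19095 CPM (0.07), ENSGALG00010016509 averaged 66367 ± 13252 and 43619 ± 11321 CPM (−0.60), and ENSGALG00010000018 averaged 17913 ± 4549 and 14721 ± 3328 CPM (−0.28). None of these passed in edgeR's main test, while ENSGALG00010016509 passed with either looser filter on low counts and VPS13A without the 3 libraries that stood apart.

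The first principal component of the 500 most variable genes (28.8% of variance) set apart replicates 1 and 2 at 35 weeks and replicate 4 at 50 weeks. On the second (16.7%) all 10 libraries were separated by age. The closest scores there were 0.90 for replicate 1 at 35 weeks and 2.09 for replicate 4 at 50 weeks. Among genes picked because they differed in these libraries, the collagen gene COL6A2 had 97, 124 and 226 counts in them and 1 to 38 in the other 7, and the actin gene ACTB had 93, 76 and 74 against 11 to 22. SCNN1A, a sodium channel subunit gene, had 97 counts in replicate 4 at 50 weeks against 6 to 21 in the other 9. The mean distance between hens of the same age was 24.2 at 35 weeks and 21.9 at 50 weeks in log2 CPM units. The difference of −2.29 was not past the threshold (exact two-sided permutation p = 0.302). Without replicate 4 at 50 weeks it was −5.22 (exact permutation p = 0.0159). Without all 3 libraries that stood apart it was −1.128 (exact permutation p = 0.543 over 35 assignments).

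**Figure D3:**
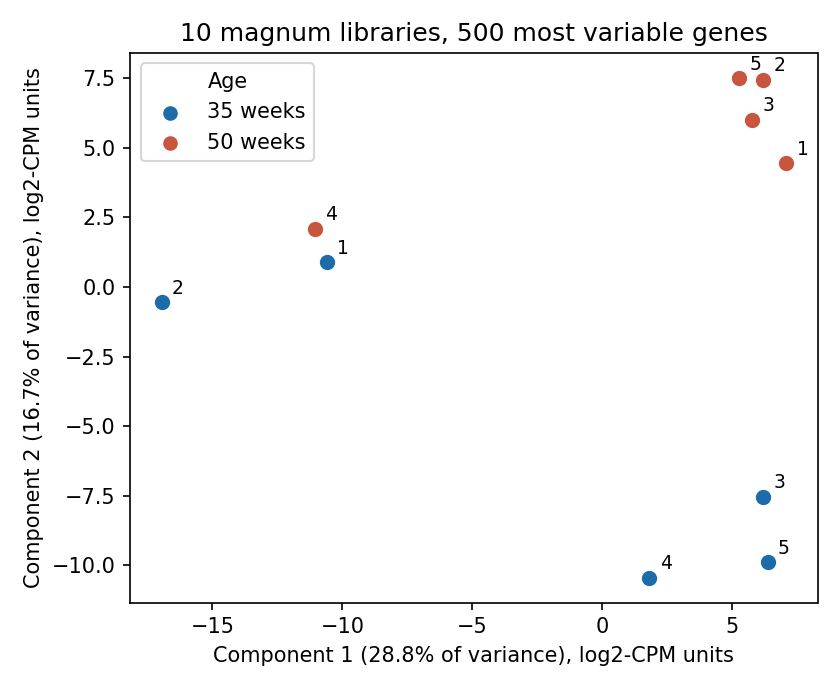
Libraries plotted by their scores on the first (28.8% of variance) and second (16.7%) principal components of log2 CPM over the 500 most variable genes, with a replicate number beside each point and colour for age. Replicates 1 and 2 at 35 weeks and replicate 4 at 50 weeks lie at low scores on the first component, away from the other 7.

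Several genes that most cells express at high levels had few counts here. They were picked after their values were seen. GAPDH had 1 to 7 counts per library, RPL3 1 to 7, EEF1A1 29 to 84 and the chaperone gene HSPA5 39 to 80. All 68 cytosolic ribosomal protein genes together held 0.309% to 0.471% of a library's counts. The 49 other genes that overlap them or lie within 1 kb of them held 1.70% to 2.40%. A few neighbours carried most of that share: the median neighbour averaged 0.9 counts and the median ribosomal protein gene 4.1, and the neighbour had more counts in 20 of 50 pairs. The 2 neighbours with the most counts were SURF1, beside RPL7A, with 848 counts against 35 for RPL7A, and ATP6AP1L, beside RPS23, with 769 against 3.7 for RPS23. RABEPK, beside HSPA5 on chromosome 17, averaged 10943 ± 2475 CPM at 35 weeks and 6438 ± 2716 CPM at 50 weeks, and HSPA5 averaged 285 ± 59.3 and 247 ± 36.8 CPM. The strand setting of the counting is not given in the sources used here, so the count of any gene is uncertain. Where a gene has a close or overlapping neighbour, its count may also come from that neighbour's RNA. Among the genes with the smallest p this holds for TIMM13, TF, ZMYM3, LRRN3, SENP8, VASH1, UTP3, IFT43 and NUDT2. It also holds for VPS13A, CALR and the egg white genes RBP, LYZ, ORM1, CLU, CST3, EXFABP and SERPINB6. From the other lists it holds for SRP14, SSR2, HSD11B2, HSP90AA1, EIF2S1, EIF3A, RPL6, NDUFB9, FTH1, DMA and TAPBP. Further such members are BIRC5, KIF20A, DNAJA4, HSPE1, CCDC65, SPEF2, SCNN1A, LITAF and JCHAIN. For AGK, POMGNT2, OVALY, SPINK7 and HSP90B1 the annotation used gives no such neighbour, but this does not settle the strand of their counts. NHERF4, HDGFL3, MUC6, ATP5PF, NFE2 and the named genes without a symbol had no coordinates.

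The authors' deposited table of their own comparison lists 203 genes, 99 with a positive and 104 with a negative log2 fold change. All 203 signs in the authors' deposited table were opposite to the difference of 50 minus 35 weeks in the counts, so a positive value there stands for a higher level at 35 weeks. The authors' deposited table gives an adjusted p for 94 of its genes, 6 of them under 0.05, an unadjusted p under 0.05 for 182, and a mean normalised count under 10 for 152. For TIMM13 the authors' deposited table gives a log2 fold change of 1.81 with a p of 7.4e-14, and for HSP90B1 1.29. Of the 203 genes in the authors' deposited table, 44 had enough counts to be tested here by edgeR, and all 44 had the same direction, 36 with an unadjusted p under 0.05 and 1 past the threshold. With DESeq2 on the same counts, all 203 had the direction of the authors' deposited table and 9 passed. The authors' genes were selected from these same libraries, so a shared direction was bound to follow and is not a replication.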

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

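The tests on the low counts of abundant genes and the test on shell gland tissue were set before their results were seen. The other tests here, on the egg white list, on the other features of the 3 libraries that stand apart and on other groupings of the libraries, were chosen only after the result was seen.

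The low counts of genes such as GAPDH and the ribosomal proteins, some of which lie beside neighbours with many more counts, may come from counting reads of a strand-marking kit on the strand opposite to the transcripts. Of the 100 most counted named genes, 88% overlap or lie within 1 kb of another gene, above the share in 99.64% of random sets matched on length (median 77%). This met the bound set beforehand for a strand error. It cannot decide, because the sets were not matched on expression, the neighbours' strand is not known, and strongly expressed genes could lie near others under either setting. Loss or splitting of reads from multicopy families was not decided. Oxidative phosphorylation subunits had a median count at percentile 54.0147 of detected genes, which met the bound set beforehand against such a loss. That result cannot decide, because a strand error could lower these genes whether or not multicopy reads were also lost. No biological explanation was tested. Other strand tests did not decide: the neighbour had more counts in 40% of 50 ribosomal pairs, so that in most pairs it did not, and the median count of genes beside ribosomal protein genes lay at percentile 92.54 of random sets. ND6, the mitochondrial gene on the other strand, had the highest count in 0 of 10 libraries, which met the bound set beforehand against a strand error, but that bound is not applied, a choice made after seeing that raw counts depend on gene length (per kb ND6 was highest in 7 of 10), so the strand of the counts stays open and a value printed for a gene could belong to RNA of the opposite strand.

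The lower egg white list at 50 weeks is not a grouping that chance readily gives: of 100 splits of the libraries, 1, the real one, had a camera p as small (5.9e-08, against 2.3015e-06 for the smallest of the others, which keeps 4 of 5 hens of each age together, and 0.00084 for the smallest of those that keep 3). The 3 libraries that stand apart stay open as a cause: without them the median was −0.38654, and the list passed by camera with its preset correlation (adjusted p = 0.00558) but not with an estimated correlation (adjusted p = 0.737, against 0.0686 with all libraries) or with fry (0.104), and the difference in share no longer passed. A smaller share of counted reads for all strongly expressed genes stays open: the log2 ratio of egg white counts without OVAL to ribosomal protein counts without RPL3L differed by −0.4655 between 50 and 35 weeks (exact permutation p = 0.00794), but the ribosomal protein list had 10 of 14 members negative and the chaperone list 9 of 10, and these low counts are themselves uncertain. A smaller share of secretory cells cannot be told apart from a lower level per cell, since 6 of 11 marker lists of other cell types had a higher sum at 50 weeks and none passed, and an effect of age itself remains an untested possibility.

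Replicates 1 and 2 at 35 weeks and replicate 4 at 50 weeks stand apart on the first principal component. A larger share of reads counted on the transcribed strand was not decided: ribosomal protein genes had a median weight above 99.71% of random lists of like expression, but oxidative phosphorylation subunits were at 60.1%, and 13 of 30 lists lay above 95%, among them endoplasmic reticulum chaperones (99.7%), ion and water transport (99.66%), amino acid transport (99.64%), general epithelium (99.61%), egg white proteins (99.09%), apoptosis and autophagy (98.95%), vesicle traffic (97.93%), heat shock proteins (97.67%) and immediate early genes (96.64%). Shell gland tissue (percentile 76.5 for its markers) and more muscle and connective tissue (percentile 76.98) cannot be told apart from other causes, as their markers lay neither above 95% of random lists nor at their median. A difference in library size is also open, because 1 of the 3 totals lay inside the range of the other 7 and the other 2 above it. No group of the design separates these libraries, so no biological explanation was tested.

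For the number of genes past the threshold, 8 of the 100 splits, the real split among them, gave at least as many as the real 1. The highest of the others was 4, so chance is not excluded for this count. For the number of lists, 7 splits, the real split among them, gave at least as many as the real 2, the highest of the others being 3. The others that reached 2 all keep 4 of 5 hens of each age together, so they hold most of the age contrast. No split that keeps 3 of 5 together reached 2. The splits therefore do not decide whether chance gives this number, and chance is not excluded. The number of genes at an unadjusted p under 0.05, 186, was reached in 3 of the 100 splits, the real split among them. The highest of the others was 205. The others that reached it put replicates 1 and 2 at 35 weeks and replicate 4 at 50 weeks, the libraries that stand apart, into the same group.

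In 138 groups of 5 libraries, 7 held a library far from the other 4 by Dixon's criterion, and chance gives about 1 in 20 groups. Replicate 4 at 50 weeks had 374.86 CPM of SCNN1A against 27.1 to 46.3 in the other hens of that age and 228 CPM of GPX8 against 22.5 to 73.6. Replicate 1 at 50 weeks had 1231.5 CPM of LYZ against 537 to 687, and 63.781 CPM of VMO1 against 0 to 18. Replicate 3 at 50 weeks had 68614 CPM of ENSGALG00010001532 against 107610 to 116410, and with it 7.2399% of its counts in its most counted gene against 10.7% to 11.8%. Replicate 1 at 35 weeks had 207.84 CPM of OVST against 118 to 136.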

How the results depend on the processing

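The comparisons without the 3 libraries that stood apart were chosen after seeing the data, and all other settings were fixed beforehand. Of 1158 values of single named genes under the alternatives, 1073 kept their direction and side of the threshold, 63 kept their direction and newly passed, and 22 turned. Where a value changed, the cause was not tested, apart from filters that change the number of genes adjusted over. The number of genes was 1 (0 higher, 1 lower) under RLE factors, library totals only, normalization without egg white genes and a fold of at least 2. It was 36 (13 higher, 23 lower) with no filter, 40 (15 higher, 25 lower) with CPM of 1 or more in at least 5 libraries, which at this depth keeps 7900 genes and so is the laxer filter, 20 (6 higher, 14 lower) with DESeq2, 12 (3 higher, 9 lower) with limma-voom, and 43 (13 higher, 30 lower) without the 3 libraries. Leaving out 1 library gave 1 to 12 genes, 0 to 5 higher and 1 to 7 lower, with 12 on leaving out replicate 4 at 50 weeks. The number of lists past the threshold, 2 in all libraries, was 0 with an estimated correlation, 1 with fry, 1 without the 3 libraries and 1 to 3 on leaving out 1 library. The egg white list had an adjusted p of 0.0686 with an estimated correlation and 0.0117 with fry, and the chaperone list 0.248 and 0.0718. The egg white genes past the threshold over the list alone, 9, were 3 without the 3 libraries and 5 to 10 on leaving out 1. The difference in egg white share stayed negative and past the threshold under every setting fixed beforehand and was −0.848 (p over it) without the 3 libraries. The difference in distance between hens was −5.22 to −0.826 on leaving out 1 library, past the threshold only without replicate 4 at 50 weeks. Without the 3 libraries it was −1.128 (exact permutation p = 0.543). Against the authors' deposited table, DESeq2 tested 203 of its genes and edgeR 44. Over all 1773 tested genes the difference in distance was −2.685 (exact permutation p = 0.3095), and the larger fixed number of variable genes was not run because it exceeds these.

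The replicate numbers do not pair the hens: same-numbered libraries had correlations of their deviations between −0.115 and 0.0979, and 2 of 5 numbers matched best with themselves. The replicate block gave 2 genes, 0 higher and 2 lower. It also took the ribosomal protein list past the threshold (adjusted p = 0.0368) and gave SPINK5 a log2 fold change of −0.033, opposite to that without it. Directions that turned with limma-voom were those of SPINK5 (−0.16), CST3 (−0.047) and SCNN1A (−0.42). Without the 3 libraries these also turned (−0.16, −0.17 and −0.48), as did CLU (0.034), MUC6 (−0.27), EXFABP (0.19), SSR2 (−0.11), HSD11B2 (0.13), LITAF (−0.044) and the ribosomal protein list (adjusted p = 0.985). On leaving out 1 library, the log2 fold change ranged from −0.14 to 0.090 for CLU, −0.15 to 0.085 for SPINK5, −0.068 to 0.13 for CST3, −0.0011 to 0.75 for MUC6, −0.84 to 0.91 for SCNN1A, −1.25 to −0.60 for EXFABP, 0.094 to 0.47 for SSR2, −0.80 to −0.12 for HSD11B2, 0.18 to 0.66 for LITAF and 0.27 to 1.29 for GPX8. Fold changes that kept their direction there included −0.26 to −0.025 for OVST, −0.37 to −0.088 for BIRC5 and 0.045 to 0.34 for KIF20A. Those of HSPE1 (0.20 to 0.50) and SRP14 (−0.32 to −0.058) also kept it. The adjusted p ranged from 0.664 to 0.933 for ciliated epithelium, 0.751 to 0.902 for the translocon list and 0.751 to 0.98 for heat shock proteins, each turning its direction in at least 1 of these fits. Depth limits which genes could be tested: with a median of 220938 counts, 1773 of 15792 genes with a count were. In the simulation, where 200 genes changed, 55.9% of 2-fold changes were recovered. That share does not carry over to the real comparison, where 1 gene passed, and its dependence on depth was not tested.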

Other observations

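AKAP9, CDH4 and RABEPK were picked after their values were seen. Each overlaps or lies within 1 kb of another annotated gene, so its count is uncertain. AKAP9, which anchors protein kinase A at the Golgi and centrosome, averaged 1120 ± 374 CPM (SD, n = 5) at 35 weeks and 478 ± 216 CPM at 50 weeks, a log2 fold change of −1.23 (SE 0.32). It did not pass in edgeR's main test (adjusted p = 0.193) and passed in 5 of the 20 fits. CDH4, a cadherin of cell adhesion, averaged 213 ± 46.7 and 96.5 ± 53.2 CPM (−1.13, SE 0.32) and also passed in 5. RABEPK averaged 10943 ± 2475 and 6438 ± 2716 CPM (−0.76, SE 0.25) and passed in 5. AGK, POMGNT2 and OVALY passed in 6 fits each. The fits share most of their libraries, so these counts are not independent evidence.

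JCHAIN, the joining chain of secreted antibodies, averaged 43.6 ± 19.5 CPM at 35 weeks and 68.3 ± 19.2 CPM at 50 weeks, a log2 fold change of 0.63 (SE 0.33, adjusted p = 0.549 with edgeR). It was the 1 tested member of the B and plasma cell list, whose 17 genes in the table held between 9 and 34 counts per library in all. JCHAIN too overlaps or lies within 1 kb of another annotated gene, so its count is uncertain.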
